A study of Xenopus laevis with 5 samples.

How the data were processed

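The samples were testes of Xenopus laevis, the African clawed frog, from animals kept from an early tadpole stage for 90 days in water with 0 or 100 µg/L of simazine, a chlorotriazine herbicide. There were 2 control arrays and 3 simazine arrays, and each array held the RNA of 1 sample. Per the labels, total RNA was extracted, amplified to Cy3-dyed cRNA and hybridised to one-colour Agilent arrays. The series text speaks of separate testes and does not say that they came from separate animals. The p-values therefore measure the spread between these samples, which may in part be technical.

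The main values were the intensity readings in the authors' deposited scanner tables, which are linear and were made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal in these tables is background-subtracted and, per the file headers, was also corrected for a multiplicative trend over the array on the 3 arrays of slide 2 and not on the 2 arrays of slide 1. The authors also deposited a table of log2 values for 27228 probes. A comparison with the scanner tables found that these values equal log2 of the processed signal minus 1 constant per array, over a selection of probes whose rule is not given in the sources used here. Their medians were 1.06, 0.951, 0.958, 1.02 and 0.949 for control 1, control 2 and simazine 1, 2 and 3. Which statistic set the constant of each array stays unknown. No mean signal of each spot was given in the scanner tables. The normexp alternatives, planned on mean signals, therefore used the median signal with the median local background and an offset of 50.

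The array held 43803 gene spots for 43653 gene probes, of which 50 probes were spotted 4 times. Spots of 1 probe were averaged. Gene names came from the supplied table of RefSeq accessions and symbols. Of 36331 accessions on the array, 10012 had a symbol, which gave 16032 named probes for 8258 genes. Control spots were left out. Spots marked non-uniform or outlier by the scanner software were left out as planned, and saturated spots (1 on control 1 and 1 on simazine 2) were kept.

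Each array's processed signal was set on the log2 scale relative to its 75th percentile. Probes were tested if they were well above background, as the scanner software judged it, on at least 2 of the 5 arrays and had at least 3 values with 1 or more in each group. The comparison was simazine minus control, fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment over all probes tested. The threshold was an adjusted p of 0.05. A looser count took probes with a fold of 2 or more and an unadjusted p under 0.05. A gene was represented by its brightest probe, by the mean over all 5 arrays. The number of arrays limits the precision of every value.

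Marked spots took 44.0% and 42.6% of the gene spots on control 1 and simazine 2 and 5.78% to 10.0% on the other arrays. Leaving them out left 14315 of the 31883 tested probes with values from slide 2 only, and 13219 with values on all 5 arrays. After the data were seen, a second set of values was therefore made with marked spots kept. Probes called on it lay together on the array, so a filter on position was added too. For each spot and array, the deviation from the 5-array median was taken as a median over the surrounding 5 rows and 9 columns, centred per array. A spot was left out on all arrays where this local deviation was over 0.5 on the log2 scale on any array. This filter does not use the groups, and its limit was chosen after the values were seen. It removed 11223 spots, or 25.6%. Some of the areas removed nonetheless followed the groups, and local deviations of up to 0.5 on each array stay in the values. In what follows, the planned values are those with marked spots left out. The position-filtered values are those with marked spots kept and the distorted areas left out.

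Gene lists were fixed before the data were examined, with 21 lists of pathways and complexes and 15 lists of markers for cell types that the samples hold or could hold. They were tested on the limma statistics with camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry, and adjusted over the 36 lists (35 lists had enough members after the position filter). A list needed 5 measured members. Genes were named by a rule fixed in advance. For rises and falls it used only genes with an informative symbol, which left out provisional symbols (those that begin with loc, mgc, xb and a number, and the like). It took the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between groups. Where fewer passed, it was filled with the smallest unadjusted p among such genes with a log2 difference of at least 1 in size. It also took up to 4 members per list that passed over all genes or over the list alone, or else the 2 members with the smallest p, and the genes star, cyp11a1, cyp17a1, hsd3b, cyp19a1, ar, esr1, amh, dmrt1, sox9 and insl3. The same rule for rises and falls was applied to the position-filtered values. Where no array of a group was well above background for a gene, the fold is given as a lower bound. It sets the mean of the brighter group against a mean of, per array, the higher of the gene's own signal and the lowest signal well above background. It makes no allowance for the distorted areas.

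The files placed control 1 and simazine 2 on slide 1, and control 2, simazine 1 and simazine 3 on slide 2. Slide was fitted as a block, and differences within each slide are given beside the results. Replicate numbers were given here in accession order and pair no samples. Alternatives covered background correction, normalization, the filter on dim probes, the variance model, array weights, slide as a block, the source of values, the set test, the probe chosen for a gene, a minimum fold of 1.2 (treat), an adjusted p of 0.1, and leaving out each array in turn. Fits without control 1 or control 2, on slide 2 alone, or of probes with 1 control value have a lone control, which limma assumes to vary like the simazine samples. The planned values have 1 control value for 17039 of 31883 probes.

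The fits were tested on simulated data with changes planted in 40 probes of each size. On the planned values (31883 probes), 0% of probes planted at a log2 change of 3, 10% at 4 and 22.5% at 6 were recovered, and 100% of those at 6 passed the looser count. On the position-filtered values (26917 probes) these shares were 7.5%, 37.5% and 77.5%, with 0 false calls. With slide as a block on the position-filtered values, 85% of probes planted at 2 were recovered, and 11 of 163 calls were false. With marked spots kept (36381 probes), 1.4% of 500 random lists passed an unadjusted p of 0.05 with camera, and 100% of 50 lists shifted by -1 did. For every set of values, the simulated means, spreads and slide shifts came from a slide-block fit of values with marked spots kept. The planned rates thus carry the spread of marked spots, and the better recovery with the block is in part built in. The simulated noise was independent between probes and held no distorted areas. These rates therefore do not test the preset correlation on the measured values, where genes of a list may vary together.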

Results

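Gene expression was measured in testes of Xenopus laevis after 90 days in water with 0 µg/L (2 control samples) or 100 µg/L of simazine (3 samples). Simazine is a herbicide of the chlorotriazine class, and the question was which genes it changes in developing males. Each sample was hybridised to 1 one-colour array of 43803 gene spots. The 75th percentile of the processed signal was 6693 on control 1, 2380 on control 2, 2476 on simazine 1, 4883 on simazine 2 and 1564 on simazine 3. The share of spots well above background was 82.1%, 78.3%, 70.7%, 85.1% and 69.1% in the same order. The first principal component held 48.7% of the variance and set both arrays of slide 1 (control 1 and simazine 2) on 1 side and the arrays of slide 2 on the other. The second held 33.95% and set the control arrays apart from simazine 2 and 3, with simazine 1 near 0. Correlations across probes between pairs of arrays lay between 0.906 and 0.966.

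Simazine testes held far less RNA of genes known from eggs and oocytes than control testes. Over the oocyte list, fixed beforehand, the mean log2 difference (simazine minus control) on the planned values was -2.34 (SE 0.342 over 29 genes, median -1.85), and all 29 values were below 0. The falls passed adjustment over the list alone for 18 of the 29 genes and adjustment over all genes for 0. Among them were pou5f3.3, a maternal POU-domain factor, at -6.03 (SE 0.345, n = 1 control and 3 simazine values), h1-8, the oocyte linker histone, at -5.08 (SE 0.326, n = 1 and 2), vegt, a maternal T-box factor, at -4.22 (SE 0.431, n = 1 and 3), and npm2, the egg histone chaperone nucleoplasmin, at -3.20 (SE 0.272, n = 1 and 3). Of the 29 genes, 24 had 1 control value, which limma assumes to vary like the simazine values. Their adjusted p over the list alone was 0.00587 for vegt, h1-8 and npm2. The list as a whole fell (camera, adjusted p = 4.16e-21, and adjusted p = 0.129 with an estimated correlation). With slide as a block its adjusted p was 6.18e-18, and its mean difference was -2.49 within slide 1 and -2.35 within slide 2.

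The position-filtered values were chosen after the data were seen, and on them the oocyte list had a mean of -2.51 (SE 0.376 over 31 genes). Of these, 10 genes fell past the threshold over all genes and 19 adjusted over the list alone. The list fell (adjusted p = 5.37e-39, and adjusted p = 0.191 with an estimated correlation; 1.05e-28 with slide as a block), with means of -2.57 within slide 1 and -2.40 within slide 2. The gene pou5f3.3 was 64.3-fold lower (log2 -6.01, SE 0.304, adjusted p = 0.0110). The egg envelope gene zp4 was 63.1-fold lower (log2 -5.98, SE 0.652, adjusted p = 0.0461, and 0.0542 with slide as a block), and zpax, another egg envelope gene, fell too, with 1 simazine array well above background, so no fold is given for it. The oocyte importin kpna7 was 50.1-fold lower, h1-8 43.4-fold, and wee2, a kinase that holds oocytes in arrest, 30.3-fold. The remaining 4 were 42sp50, a protein of the RNA storage particle of young oocytes (25.4-fold), the RNA-binding protein zar1 (19.1-fold), the forkhead factor foxr1 (14.3-fold) and npm2 (10.9-fold). The brightest probes of kpna7 and zpax lie in distorted areas, and these values come from another probe of each. Probes disagreed for vegt, whose brightest probe gave -0.22 here and its other probe -4.07, and in part for 42sp50, whose other probe gave -1.95. The brightest probe of vegt thus did not bear out the planned value of that gene given above. Among planned values, the oocyte call ended when only probes with no marked spot on any array were used (mean -1.55, adjusted p = 0.101).

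**Figure D1:**
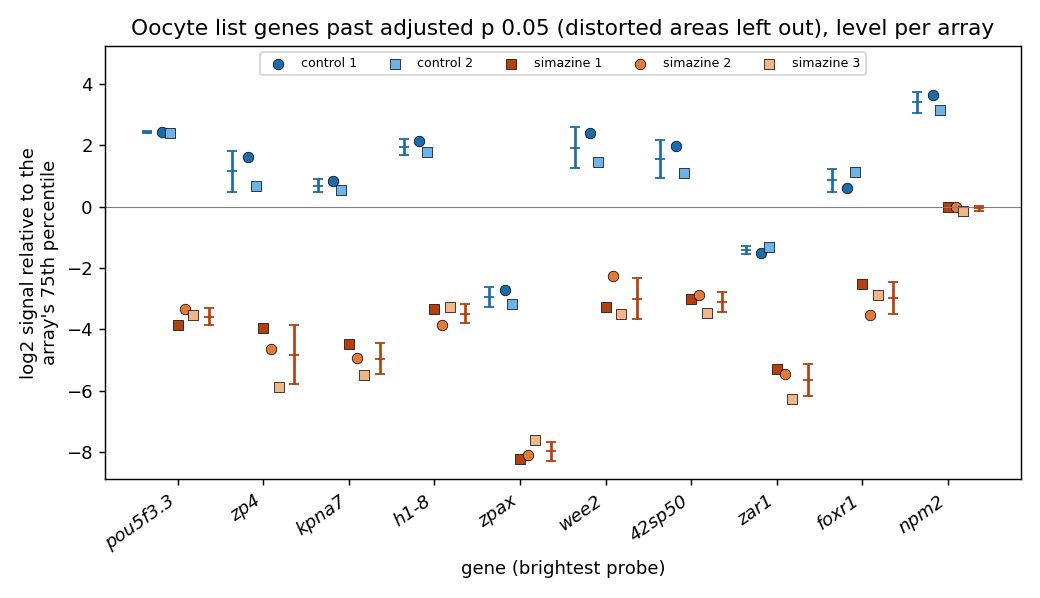
Level of each of the 10 oocyte list genes past the threshold on the position-filtered values, as log2 signal relative to the array's 75th percentile, with 1 point per array (circles for slide 1, squares for slide 2) and the mean and SD of each group beside the points. Both control arrays lie above all 3 simazine arrays for each of these genes, for pou5f3.3 with a mean of 2.43 against -3.58.

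Over all probes, few calls passed. On the planned values 1 of 31883 probes passed the adjusted p of 0.05, an unnamed probe lower in simazine (log2 -6.34, SE 0.202, adjusted p = 0.0348), with -6.22 within slide 1 and -6.47 within slide 2. This probe falls outside the naming rule and was singled out after its value was seen. The number past a fold of 2 and an unadjusted p of 0.05 was 2460 (762 higher and 1698 lower), and 2709 passed the unadjusted p alone, where chance gives 1594. Other groupings of the same arrays also gave high counts past the fold and unadjusted p (limma). The count was 3969 with control 1 and simazine 2 set against the rest, and 2351 with simazine 1 and simazine 3. The remaining splits gave 411 to 1583. The excess over chance can therefore not be credited to simazine alone. Without the filter on dim probes, 3032 passed the fold of 2 and unadjusted p (limma), 1408 higher and 1624 lower. Of 7310 genes, 0 passed with limma adjusted over all probes. Under a slide block 0 of 31111 probes passed (limma), with 3797 at an unadjusted p under 0.05. Leaving out any 1 array gave 0 calls with limma, and 1245 to 3058 probes past a fold of 2 and unadjusted p of 0.05.

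After position filtering, 99 of 26917 probes passed, 96 lower and 3 higher in simazine, and 48 of 6868 genes fell and 0 rose. The number past a fold of 2 and an unadjusted p of 0.05 was 823 (208 higher and 615 lower). The number past an unadjusted p of 0.05 alone was 1030, where chance gives 1346. Without the filter on dim probes, 1215 passed the fold of 2 and unadjusted p (limma), 625 higher and 590 lower. Under a slide block 254 probes passed (17 higher and 237 lower), with 2944 at an unadjusted p under 0.05 (limma). Without control 1, control 2, simazine 1 or simazine 3 the count was 0 with limma, and without simazine 2 it was 45. Leaving out 1 array left 699 to 1549 probes past a fold of 2 and an unadjusted p of 0.05. With both marked spots and distorted areas left out, 1 of 23510 probes passed.

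Among genes with an informative symbol, the 12 largest falls past the threshold on the position-filtered values were cldn6.1, a claudin of tight junctions (log2 -6.74, SE 0.589, adjusted p = 0.0282), zfp36l2.2 (-6.62), the histone gene h2ac17 (-6.25), grhpr.2 (-6.21), pou5f3.3, rnf138 (-6.003), zp4, the oocyte connexin cx38 (-5.73), kpna7, btg5.1 (-5.50), h1-8 and upk3a, a uroplakin (-5.42). All 3 simazine arrays lay below both control arrays for each, as the naming rule requires, and zfp36l2.2 was well above background on 1 of the simazine arrays. Other probes gave -6.88 for cldn6.1, -6.14 for grhpr.2 and -5.33 for cx38. Under a slide block, zp4 alone of these 12 missed the threshold. The naming rule found 0 rises past it with limma. The rises that filled it were led by prss3, a trypsin (2.44, SE 0.301, adjusted p = 0.0708, and 0.0334 with slide as a block), cygb, cytoglobin (2.44, SE 0.317, adjusted p = 0.0797, and 0.0406 with slide as a block), and serpina3 (1.90, adjusted p = 0.163, and 0.0406 with slide as a block). The other 9 were cela1.4 (3.23), tnni3 (1.42), atf6 (1.85), b9d2 (1.42), bivm (1.41), zpbp2 (1.27), srf (1.12), rpe65 (1.15) and ribc2 (1.17), with adjusted p between 0.192 and 0.700. For prss3, cygb and cela1.4, 1 of the control arrays was well above background.

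On the planned values no named gene passed over all probes, and the rule was filled with 12 genes of informative symbol on each side, with adjusted p from 0.0507 upward. The negative values were upk1a, a uroplakin (-4.33, SE 0.224, adjusted p = 0.0507), sptssb (-3.61), zfp36l2.2 (-6.43), coro2a (-2.88), germes, a germ plasm gene (-6.66), rnf138 (-5.77), cldn6.1 (-7.61), stmn2, a neuronal stathmin (-3.32), pou5f3.3, sncg, a synuclein (-2.62), cldn6.2 (-6.58) and pex3 (-3.07). Of these, sptssb, coro2a and germes lie in distorted areas, and sptssb, zfp36l2.2, coro2a, germes and pex3 were well above background on 1 of the simazine arrays. The positive values were pax5, a B-cell factor (3.66, SE 0.240, adjusted p = 0.0507), zmiz2 (5.94), cnrip1 (4.17), kpna3 (4.12), alg1 (6.58), cd74, a leukocyte invariant chain (2.40), rwdd2a (5.63), rnf14.4 (4.26), acads (4.63), fdx2 (2.49), scpep1 (5.01) and itsn1 (3.95). All 12 of them lie in distorted areas. For pax5, 0 of 2 control arrays were well above background, and the bound on its rise in simazine was 6.61-fold. This bound makes no allowance for local dimming, which reached -3.10 on control 1 and -2.87 on control 2 (log2, strongest on each array). The true rise can therefore be smaller. For rwdd2a, rnf14.4 and fdx2, 1 control array was well above background. Other probes of the same genes gave 0.53 for zmiz2, -1.55 for cnrip1, 0.26 for kpna3, 0.20 for alg1, 0.17 for cd74, -0.66 for fdx2 and -0.03 for itsn1.

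**Figure D2:**
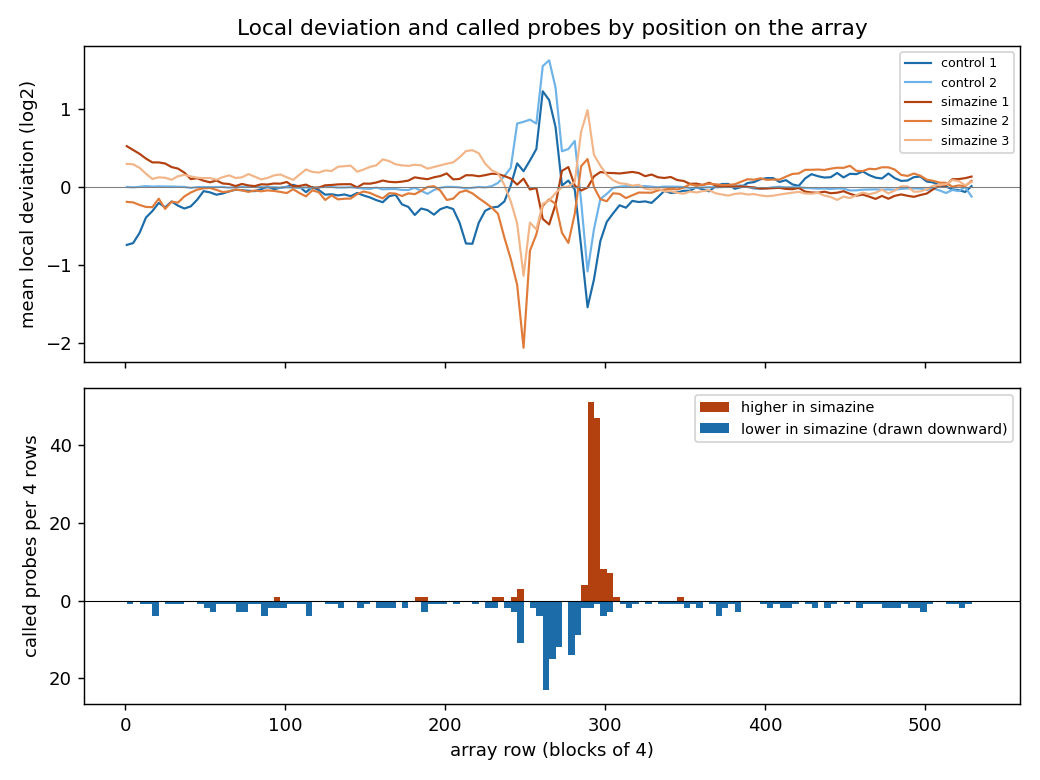
Upper panel: mean local deviation of each array (log2) by position along the array, in blocks of 4 rows. Lower panel: called probes per block with marked spots kept, higher in simazine upward and lower downward; of 128 called higher, 118 lie in the 25 rows from 281 to 305.

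Position on the array went with the calls. With marked spots kept, 372 of 36381 probes passed, 128 higher and 244 lower in simazine. Distorted areas held 26.1% of the tested probes, 96.9% of those called higher (124) and 46.3% of those called lower (113). The share of spots past the limit of local deviation was 12.8% on control 1, 7.53% on control 2, 6.002% on simazine 1, 7.71% on simazine 2 and 10.4% on simazine 3. Some distortion followed the groups on both slides. In the block from row 265, the mean local deviation was 1.11 and 1.62 on controls 1 and 2. It was -0.48, -0.16 and -0.18 on simazine 1, 2 and 3. From row 289 it was -1.54 and -1.08 on the controls and -0.01, 0.36 and 0.98 on the simazine arrays. Other areas, such as that from row 213, did not split by group. Outside the distorted areas, other probes of 27 genes called lower had a median of -3.16 (95% interval -4.92 to -2.22), and 22 of them were lower by 1 or more.

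The germ line list fell on the planned values (mean -2.12 over 13 genes, adjusted p = 6.01e-04, and adjusted p = 0.526 with an estimated correlation), with 5 falls adjusted over the list alone and 0 over all genes. They included germes, pou5f3.3, nanos1, a translational repressor of the germ plasm (-4.61), and pgat, a germ plasm gene (-5.01); nanos1 and pgat were well above background on 1 simazine array. With slide as a block its adjusted p was 0.00536, and its mean was -2.04 within slide 1 and -2.33 within slide 2. Without 3 members shared with the oocyte list, the other 10 genes had a mean of -1.51, which camera called before adjustment; after position filtering the other 15 had a mean of -0.40, which it did not. Leaving out germes and pgat too, chosen after their values were seen, gave a mean of -0.42 over 8 genes, which camera did not call. The call ended without control 1 (mean -1.32, adjusted p = 0.136) or without control 2 (adjusted p = 0.242), each a fit with a lone control. It also ended with the authors' log2 table (mean -1.35, adjusted p = 0.0729), with only probes well above background on all arrays (mean -0.99, adjusted p = 0.407) and with only probes that had no marked spot (mean -0.98, adjusted p = 0.890). Its position-filtered mean was -0.95 over 19 genes, with a median of 0.01, and camera called it lower (adjusted p = 0.0354, 0.0880 with slide as a block, and adjusted p = 0.630 with an estimated correlation). That call ended without control 2 or simazine 2 (adjusted p = 0.317 and 0.203), and on slide 2 alone (0.0708). It ended under normexp with quantile normalization (mean -0.54, adjusted p = 0.0950) or the 75th percentile (-0.51, 0.0534), quantile normalization (0.0894), array weights (0.430), the mean of all probes (0.196) and fry (0.140). Probes well above background on all arrays (-0.36, adjusted p = 0.761) and probes with no marked spot (0.542) ended it too. On those values 2 members, pou5f3.3 and pgat, fell over all genes and 4 adjusted over the list alone.

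Epithelial and cell cycle genes fell as lists on the planned values. The epidermis and keratin epithelium list had a mean of -1.11 over 18 genes on the planned values, with a median of -0.15 (adjusted p = 0.0213, and adjusted p = 0.526 with an estimated correlation). Its 4 falls adjusted over the list alone were cldn6.1, upk3a (-5.48), upk1b, another uroplakin (-1.57), and the cell adhesion gene epcam (-2.55), whose probe lies in a distorted area. Its mean was -1.35 within slide 1 and -1.04 within slide 2, and -0.92 with slide as a block (adjusted p = 0.126). The cell cycle list had a mean of -0.39 over 79 genes (adjusted p = 0.0213, and adjusted p = 0.526 with an estimated correlation). Only birc5, a component of the chromosomal passenger complex, fell adjusted over the list alone (-5.20, SE 0.351). The list's mean was -0.33 within slide 1 and -0.40 within slide 2, and -0.27 with slide as a block (adjusted p = 0.126). The calls of both lists ended on leaving out any 1 array, with adjusted p between 0.0929 and 0.796 for the epidermis list and between 0.112 and 0.513 for the cell cycle list, whose mean then lay between -0.27 and -0.79; without 1 control these fits have a lone control. The epidermis call also ended with normexp and quantile normalization (adjusted p = 0.0544), the authors' log2 table (0.107), no filter on dim probes (0.0653) and the mean of all probes (0.0971). The cell cycle call also ended with normexp and quantile normalization (adjusted p = 0.0741), fry (0.05996), marked spots kept (0.288, and 0.213 with the block) and slide 2 alone with marked spots kept too (0.226). With only probes that had no marked spot the means were -0.09 for the epidermis list and -0.17 for the cell cycle list (adjusted p = 0.890 for each). Both lists were called lower again on the position-filtered values, the epidermis list with a mean of -0.79 (adjusted p = 0.00982, and adjusted p = 0.530 with an estimated correlation; 0.0215 with slide as a block) and the cell cycle list with a mean of -0.32 (adjusted p = 0.00858, and adjusted p = 0.396 with an estimated correlation; 0.00795 with slide as a block). There the calls of both lists ended without control 2 (adjusted p = 0.0868 and 0.183) or simazine 2 (0.0795 for each), and the cell cycle call ended at local deviation limits of 0.3 (mean -0.21, adjusted p = 0.140) and 1 (-0.21, 0.111) and with the authors' log2 table (-0.25, 0.0874). The epidermis call ended with array weights (adjusted p = 0.0618), and both with fry (0.140 for each). With only probes that had no marked spot the epidermis mean turned to 0.14 (adjusted p = 0.893), and the cell cycle mean was -0.12 (adjusted p = 0.540). Adjusted over all genes, birc5 and the replication licensing gene mcm3 (-3.03) fell.

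The intestine and pancreas list rose on the planned values (mean 0.51 over 24 genes, adjusted p = 0.0102, and adjusted p = 0.845 with an estimated correlation). Over the list alone 4 members rose, among them prss3 (2.54), the protein disulfide isomerase pdia2 (1.71) and cela3b, an elastase (1.02), and lct.1, a lactase, fell (-2.02). The probes of pdia2 and lct.1 lie in distorted areas. With slide as a block its adjusted p was 0.00776, and its mean was 0.38 within slide 1 and 0.43 within slide 2. Its mean was 0.31 without control 1 and 1.17 without control 2, each a fit with a lone control. The call ended without control 1 and on slide 2 alone with marked spots also kept. With distorted areas also left out its adjusted p (camera) was 0.0629, and without simazine 1 it was 0.0976. It was 0.113 and 0.142 under normexp with quantile normalization (mean 0.22) or the 75th percentile. With only probes well above background on all arrays it was 0.371 (mean 0.29). It was 0.101 with no marked spot, 0.123 with the mean of all probes and 0.247 with fry. Its position-filtered mean was 0.38 over 16 genes (adjusted p = 0.0303, 0.0895 with slide as a block, and adjusted p = 0.630 with an estimated correlation), and this call ended without control 1, simazine 1 or simazine 2 (adjusted p = 0.485, 0.0716 and 0.0795), and at local deviation limits of 0.3 and 1 (adjusted p = 0.606 and 0.0543). It also ended under normexp with quantile normalization (mean 0.18, adjusted p = 0.171) or the 75th percentile (0.0551), with only probes well above background on all arrays (mean 0.22, adjusted p = 0.284), with the mean of all probes (mean 0.27, adjusted p = 0.194), on slide 2 alone (0.419), with no marked spot (0.493) and with fry (0.169).

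Neuron and glia markers did not pass on the planned values (mean -0.41 over 27 genes, adjusted p = 0.301), though fry called them (adjusted p = 0.0301), and stmn2 and sncg fell adjusted over the list alone. After position filtering the list had a mean of -0.57 over 22 genes and fell (adjusted p = 0.00467, and adjusted p = 0.530 with an estimated correlation; 0.0176 with slide as a block). Its mean was -0.43 within slide 1 and -0.61 within slide 2, and the call ended without control 2 (adjusted p = 0.0581) and at local deviation limits of 0.3 and 1 (adjusted p = 0.0779 and 0.163), and with no marked spot (0.138) or fry (0.140). With marked spots left out as well the list fell (mean -0.58, adjusted p = 0.00402). Skeletal and cardiac muscle markers had a mean of 0.19 over 38 genes on the planned values (adjusted p = 0.412; tnnt1 1.74, myog 0.96). Their position-filtered mean was 0.23 over 34 genes, and they rose (adjusted p = 0.0354, 0.0895 with slide as a block, and adjusted p = 0.630 with an estimated correlation), with 0 members past the threshold over the list alone (limma) and the same direction within both slides (0.29 and 0.19). The muscle call ended without control 1, simazine 1 or simazine 2 (adjusted p = 0.485, 0.106 and 0.0795), and at local deviation limits of 0.3 and 1 (adjusted p = 0.0528 and 0.168). It also ended under normexp with quantile normalization (adjusted p = 0.0576), quantile normalization (0.0571), the authors' log2 table (0.471), the mean of all probes (0.122), slide 2 alone (0.383), no marked spot (0.394), marked spots left out as well (0.119) and fry (0.304).

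Lists of sex steroid genes and of somatic testis cell types did not pass the test, and none of their members passed with limma unless slide was a block, where 1 probe of the Sertoli cell marker tf fell after position filtering (adjusted p = 0.0301) and another did not pass (0.206). On the planned values star, which carries cholesterol into mitochondria, was at 0.28 (SE 0.326), cyp17a1, the enzyme of androgen synthesis, at 0.32 (SE 0.328), hsd3b1 at -0.17 and hsd3b7 at -0.38. The aromatase gene cyp19a1 was at -0.61 (SE 0.295, n = 2 control and 3 simazine values, limma adjusted p = 0.768). The oestrogen receptor esr1 was at 0.44, the male-determining factor dmrt1 at 0.37 and the Sertoli cell factor sox9 at -0.56, and none of these passed adjusted over all probes. The probes of star, hsd3b1, esr1 and sox9 lie in distorted areas, and cyp11a1, ar, amh and insl3 were not analysed here. The steroid synthesis list had a mean of 0.06 over 20 genes (adjusted p = 0.980; cyp19a1, stard4 -0.87) and the sex steroid and gonadotropin list 0.04 over 20 genes (fshb 0.52, shbg -0.52). Sertoli cell markers had a mean of -0.00286 over 16 genes (shbg, dhh -0.68), Leydig cell markers 0.06 over 6 (nr5a1 -0.45, pdgfra 0.52) and granulosa markers 0.12 over 8 (cyp19a1, foxl2 0.51), each with an adjusted p of 0.980.

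**Figure D3:**
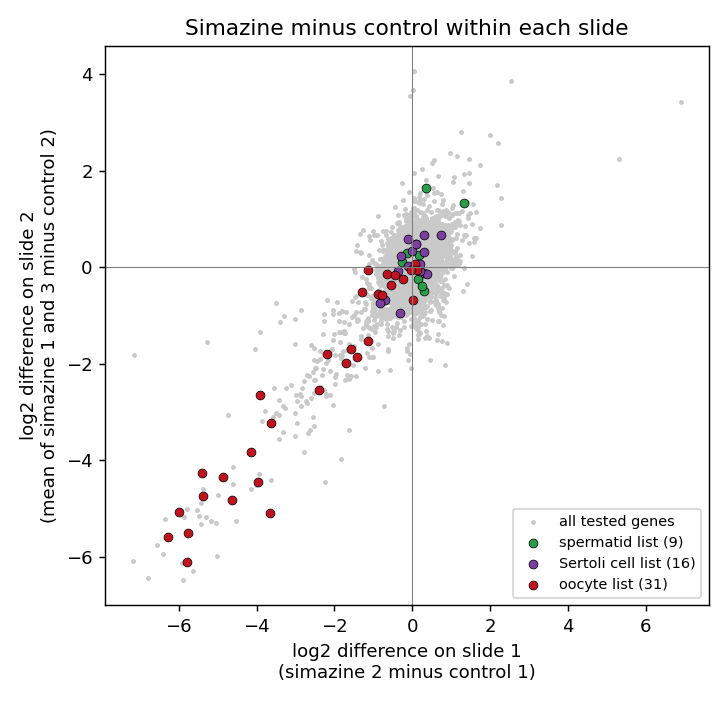
Log2 difference of each gene within slide 1 (horizontal, simazine 2 minus control 1) and within slide 2 (vertical, mean of simazine 1 and 3 minus control 2) on the position-filtered values. Oocyte list genes lie toward the lower left, with means of -2.57 and -2.40, while Sertoli cell and spermatid markers lie about the origin.

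Spermatogenic lists did not pass on the planned values. Meiotic prophase genes had a mean of -0.11 over 8 genes (adjusted p = 0.980; ccna1, a cyclin of meiosis, -2.64, and xb5904899 0.59). After position filtering another probe of ccna1 fell by 3.08 (limma, adjusted p = 0.0445), and the gene's other probe left on those values gave -1.09. Spermatid and sperm genes had a mean of 0.28 over 8 genes (adjusted p = 0.456; zpbp2 1.33, hspa1l 0.40), and motile cilium genes 0.14 over 35 (adjusted p = 0.569; tekt3 2.56, dynlt5 -1.58). After position filtering the cilium list had a mean of 0.16 and did not pass (camera, adjusted p = 0.0663, and adjusted p = 0.866 with an estimated correlation). It passed with slide as a block (0.0176). On those values 1 gene list was also called higher with quantile normalization, with or without normexp, and without simazine 1 or simazine 3. The same held with the 75th percentile over probes well above background on all arrays. Which list it was is not given here. Peritubular markers had a mean of 0.35 over 8 genes (adjusted p = 0.412; cnn2 0.60, smtn 0.67).

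Blood cell lists did not pass as lists. Leukocyte markers had a mean of 0.79 over 16 genes (adjusted p = 0.250). Their 3 members past the threshold over the list alone were pax5, cd74 and mpo, a myeloid peroxidase (6.05), all with probes in distorted areas. Erythrocyte markers had a mean of 0.08 over 17 genes (adjusted p = 0.980), and the haemoglobin genes went both ways over the list alone: hba-l5 fell (-4.79), hbe1 fell (-2.40) and hba2 rose (3.83), the last pair with probes in distorted areas. For mpo and hba2, 1 control array was well above background, and for hbe1 and irf3 1 simazine array. After position filtering hba-l5 fell over all genes (-5.20, adjusted p = 0.0154). Immune genes had a mean of -0.10 over 35 (adjusted p = 0.569; irf3 -1.36, c2 -1.34) and endothelial markers -0.07 over 9 (adjusted p = 0.980; aplnr -1.44, sox7 -0.21).

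The lists of metabolism and stress gave no call as lists in the main fits, and 25 of the 54 genes named for lists without a passing member (46.3%) lie in distorted areas. On the planned values 3 gene lists were called lower with normexp and the 75th percentile, against 2 in the main fit. After position filtering it was 3 without the filter on dim probes, again against 2. Which list was added is not given here. Ribosomal proteins had a mean of -0.54 over 52 genes (adjusted p = 0.301; rps23 -3.06, rpl36 -2.01). Arginine, proline and creatine genes had a mean of -0.11 over 34 (adjusted p = 0.456; ass1 -1.12, agmat -0.86). The means of 6 further lists had an adjusted p of 0.569 or 0.584: thyroid hormone response at 0.24 over 20 (rxrg -1.92, mmp13 -0.66), glycolysis at 0.17 over 30 (dlat 1.53, hk2 -1.15), retinoic acid at -0.11 over 14 (cyp26a1 -1.68, aldh1a3 0.85), oxidative phosphorylation at 0.13 over 35 (ndufb4 -1.57, ndufs3 1.40), kidney at 0.14 over 22 (emx1 0.58, lhx1 0.82) and fat body at -0.23 over 12 (dgat2 -2.28, lipe -0.52). Cholesterol genes had a mean of -0.20 over 15 (adjusted p = 0.592; idi1 -0.77). For sc5d among them 0 of 3 simazine arrays were well above background, so its signal was at least 2.998-fold lower in simazine, without passing the test.

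The last 7 lists had an adjusted p of 0.980. Heat shock and unfolded protein genes had a mean of -0.05 over 36 (calr -2.62, hsf1 -1.65), and hepatocyte markers 0.06 over 34 (hgd -1.23, serpina3 2.11). Antioxidant and glutathione genes had a mean of -0.12 over 34 (gpx7 -2.44, gclc -1.35), and xenobiotic metabolism genes 0.05 over 26 (cyp2a6.12 -4.05, fmo2 0.69). DNA repair genes had a mean of -0.06 over 38 (xrcc6 -2.51, fancd2 -2.58), apoptosis and p53 genes 0.04 over 35 (xiap 0.95, ccng1 0.90), and extracellular matrix genes 0.08 over 31 (col9a1 2.17, dcn -1.28). On the planned values the test at gene level did not pass for any of the genes named here for these lists. With marked spots kept, cyp2a6.12, xrcc6 and col9a1 passed (adjusted p = 0.0446, 0.0486 and 0.0464); after position filtering serpina3 passed with slide as a block. For cyp2a6.12, hgd and, above, ndufb4, 1 simazine array was well above background; for fancd2 and emx1 it was 2, and for pdgfra 1 array of each group.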

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

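All alternatives for the position-filtered values, and for the planned values those that keep marked spots, leave out distorted areas, use probes with no marked spot on any array or use slide 2 alone with marked spots kept, were chosen after the data were seen. Fits without 1 control and on slide 2 alone have a lone control, assumed to vary like the simazine samples. Where a count moved, the cause was not tested unless fewer probes, samples or a stricter test explain it. The slide block is the only block run; the replicate numbers pair no samples, so no paired analysis was possible because the labels give no shared numbers. No gene or list compared here passed the threshold in the main fit and passed it in the opposite direction in an alternative. A change of direction was counted as a reversal where the main fit or the alternative passed, and 0 were found. Where neither passed it was not counted, so directions could differ between settings. For lists the direction was that of camera, which can differ from the sign of the mean. For single genes on the planned values, 2204 comparisons kept their side of the threshold and 178 crossed it to pass. On the position-filtered values 1568 kept it, 177 no longer passed and 17 newly passed. For lists the numbers were 830, 44 lost and 8 gained, and 752, 64 and 12. The mean of the oocyte list stayed between -2.67 and -1.55 on the planned values. The mean of the epidermis list on the position-filtered values turned to 0.14 (not past the threshold) with only probes that had no marked spot. The planned mean of the skeletal and cardiac muscle list turned from 0.19 to -0.12 without simazine 1, and passed the threshold in neither fit. The median of all probes, 0.0984 on the planned values, became 0.262 with normexp and the 75th percentile. Dim probes limit the depth: 69.1% to 85.1% of spots were well above background.

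On the planned values, with 1 probe past the threshold, the count was 282 (79 higher, 203 lower) with normexp and quantile normalization, 96 (38, 58) with quantile normalization, 94 (37, 57) with median centring, 138 (50, 88) with array weights, 19 with a trend and robust eBayes, 4 with probes well above background on all arrays, 2 with the authors' log2 table and 316 at an adjusted p of 0.1. It was 0 (limma) with normexp and the 75th percentile, with a percentile over detected probes, without a filter, with the slide block, with no marked spot on any array, on slide 2 alone with marked spots kept (2 choices changed), and in each fit that left out 1 array (0 to 0). It was 372 with marked spots kept, 825 with these and the slide block, and 99 with these and distorted areas left out. The planned probe was among the calls in each of these settings with more than 0. The count past a fold of 2 and unadjusted p of 0.05, 2460 as planned, was 1358 with normexp and the 75th percentile, 1406 with probes well above background on all arrays, 1338 with no marked spot, 770 with distorted areas left out, 823 with marked spots kept and distorted areas left out, and 1245 to 3058 without 1 array. The count of gene lists, 2 as planned, was 1 with normexp and quantile normalization, the authors' log2 table, probes well above background on all arrays, the slide block, fry, marked spots kept (with and without the block, and with slide 2 alone), 0 with no marked spot or an estimated correlation, and 0 to 1 without 1 array. The count of cell type lists, 3 as planned, was 1 with normexp and quantile normalization and with the mean of all probes, 5 with marked spots kept and distorted areas left out, 0 with no marked spot or an estimated correlation, and 1 to 3 without 1 array. Of 24 genes of the naming rule, 15 kept their direction at an unadjusted p under 0.05 (limma) with probes well above background on all arrays. With no marked spot 12 did. With distorted areas left out it was 9, with 0 rises and 9 falls, whether marked spots were left out or kept. A gene without a value in a setting counted as not kept.

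On the position-filtered values, with 99 probes past the threshold, the count was 17 with normexp and the 75th percentile (all 17 among the 99), 37 without a filter (all 37), 254 with the slide block (98 of the 99), 162 at an adjusted p of 0.1, 1 with no marked spot, 1 with marked spots left out too, 0 on slide 2 alone (limma, with 1270 past a fold of 2 and unadjusted p of 0.05), and 0 to 45 without 1 array. The count past a fold of 2 and unadjusted p of 0.05, 823 (208 higher and 615 lower), became 507 (66 and 441) with normexp and quantile normalization, 416 with normexp and the 75th percentile, 512 with probes well above background on all arrays, 1260 with array weights, 292 with no marked spot, 495 and 1451 at local deviation limits of 0.3 and 1, and 699 to 1549 without 1 array. The count of gene lists, 2 here, was 1 with the authors' log2 table, probes well above background on all arrays, array weights, limits of 0.3 and 1, slide 2 alone and the mean of all probes, 0 with no marked spot, an estimated correlation or fry, and 0 to 3 without 1 array. The count of cell type lists, 5 here, was 3 with normexp and quantile normalization, the slide block, marked spots left out too, slide 2 alone and the mean of all probes, 2 at limits of 0.3 and 1, 1 with no marked spot and with fry, 0 with an estimated correlation, and 2 to 5 without 1 array. Of 24 genes of the naming rule, 3 kept their direction at an unadjusted p under 0.05 (limma) with no marked spot, 3 rises and 0 falls.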

Other observations

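Of the tests here, those of splits with marked spots kept, of other probes for 1 accession and of the distance between called spots were set before their results were seen, and the others after. Beyond the fixed lists, genes that fell past the threshold on the position-filtered values (limma) were picked after their values were seen, and no shared function was tested for them. They included h2ac17 at -6.25, sox3 at -5.35 (another probe -4.49), spire1 at -5.34, h2ac1 at -5.03 (32.8-fold), foxi2 at -2.86 (another probe -4.16) and h1-3 at -2.71 (6.56-fold). For not (-4.92) and zic2 (-3.40) the other probes did not fall (1.04 and a median of 0.10). The uroplakin upk1a (-4.33), the claudin cldn6.2 (-4.41) and the protease prss8 (-3.27) fell as well. The uroplakin upk3a, which fell too, belongs to the fixed epidermis list.

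For the 10 oocyte list genes past the threshold after position filtering, RNA was lower in all 3 simazine samples than in both controls. These genes were picked by that threshold on the same values, so the separation adds no support of its own. Slide cannot be the whole cause, since the mean of the list was -2.40 (SE 0.375, n = 31 genes) within the slide where it lay nearer 0, nor can array position, since it was -2.51 (SE 0.376) outside the distorted areas. Control samples that were whole ovaries were predicted to put Sertoli and spermatid markers higher in simazine, and these had a mean of 0.0302 (SE 0.1004, n = 25 genes). As a set these markers thus showed no rise. The fixed Sertoli cell list shares members with the granulosa list, and whether these testes held spermatids was not tested. The mean therefore cannot by itself exclude ovaries. Oocyte RNA in both control samples stays a candidate explanation, and was predicted to put most oocyte markers lower by 1 or more. Of the 31 tested, 20 were (64.5%, exact 95% interval 45.4 to 80.8, against 2.94% of 6837 other genes). The interval treats genes as independent draws and measures no spread between samples. It does not settle whether most oocyte markers beyond these 31 would move. Of the 31, 4 also stand in another list, such as ddx4 (6.52 in control, 6.77 in simazine). Oocytes within the control testes, adjoining ovarian tissue in the dissection, and fewer oocytes under simazine stay open, since no histology was analysed here.

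Probes called higher in simazine with marked spots kept may reflect their place on the array. The median distance from such a spot to the next one was 1 spot, where 1000 random sets of 128 spots gave 7.81 to 10.4. For the 244 spots called lower it was 5, where random sets of that size gave 5.83 to 7.14, so these lay closer than random sets as well. A rise of the whole gene is argued against by the other probes of 37 of these genes, with a median of 0.0157 (95% interval -0.25 to 0.229), and a rise of 1 homeolog by other probes for 39 of the accessions, with a median of 0.0778 (-0.25 to 0.132). What distorted the areas was not tested.

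The 5 arrays make 10 splits into 2 and 3, too few for a share under 0.05. With marked spots kept, 2 of the 10 gave as many probes past the threshold as the real split, itself included, with 372 for the real split and 7164 for the highest other. With distorted areas left out it was again 2, with 99 and 8457. In both cases the other split set the arrays of slide 1 against those of slide 2, which points to a structure of the samples by slide, and with slide as a block the real comparison gave 825 and 254 probes. With marked spots kept, the looser count (limma) was 2978 for the real split and 8017 for the split by slide. It was 3102 with simazine 1 and simazine 3 set against the rest.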
